A study of Mus musculus with 19 samples.

How the data were processed

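Gene expression was measured on 19 Affymetrix Mouse430+2 arrays, 1 array per sample by the titles, in 5 groups. The groups were 4 arrays of NEPs (Nestin-expressing progenitors), 4 arrays of GNPs (granule neuron progenitors, Math1-positive), 3 arrays of NSCs (CD133-positive, lineage-negative cerebellar cells), 4 arrays of tumors arising where Nestin-CreERT2 targets Ptch1 (NEP tumor) and 4 arrays of tumors arising where Math1-CreERT2 does so (GNP tumor). Per the labels' protocols, the cells were taken from mouse cerebellum without culture or treatment, RNA was extracted with Trizol, and 100 ng of total RNA was amplified with the Ambion WT Expression Kit and labelled by the Affymetrix WT terminal labelling protocol. The labels give no age, sex or pooling of animals, and nothing states that the arrays of a group come from separate animals, so every p-value measures only the spread between these arrays.

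The deposited values are log2 probe set signals that the authors made with RMA and Affymetrix Expression Console, per the submitters' processing notes, which give no version and no log base. The base was checked on the hybridisation spike-ins, RNAs added at known concentrations: the signal of Cre (100 pM) minus that of BioB (1.5 pM) was 5.41 on average over the arrays, from 5.04 to 5.78, where the concentrations give 6.06 on a log2 scale, 4.20 on a natural log scale and 1.82 on a log10 scale. Each array had the same mean over all its probe sets, 3.79, to within 2.3e-07. The background step and the centring behind that common mean are not stated. Values ran from 0.29 to 13.37, and the median of the probe sets other than controls lay between 2.44 and 2.57 on each array. No pair among the 171 pairs of arrays held identical values. The number of arrays limits the precision.

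Numbers in the array titles put the NEP and GNP arrays in one series and the NSC and tumor arrays in another, here called the first and the second run. Poly-A spike-ins, added to the RNA before labelling, gave a mean signal of 8.69 ± 0.26 (SD, n = 8) in the first run and 6.50 ± 0.27 (n = 11) in the second, 2.19 apart. Run and group cannot be told apart where a first-run group is compared with a second-run group, that is, in every comparison with NSCs and of tumors with progenitors. NEP against GNP and NEP tumor against GNP tumor lie within a run. In the test of whether these differences are unequal, a run effect that adds the same amount to both groups cancels.

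Of 45101 probe sets, 64 were controls. Among the other 45037, 34945 carried 1 gene symbol and were used, 932 carried several symbols and 9160 none, and these were left out. Symbols were matched by gene ID to the mouse gene table for 34741 probe sets, with 0 symbols changed. Each of the resulting 18193 genes took the value of its probe set with the highest mean over the 19 arrays, since 9010 genes had more than 1 probe set. Genes were tested when that probe set was at or above its array's median in at least 3 arrays, which left 12148 genes. A gene mean under the array median in a group is called dim, and its fold is then a fold of array signal.

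All arrays were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 5 group means, a variance per gene shared by all groups), with two-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p below 0.05. There were 7 comparisons: NEP with GNP, NEP with NSC, GNP with NSC, NEP tumor with GNP tumor, the difference between the tumor difference and the progenitor difference (the interaction), and each tumor with its progenitor. Differences are log2, the first group minus the second, with the standard error (SE) of the fit. Group levels are means ± SD over the arrays, with n = 4, or n = 3 for NSC. A gene was NEP-enriched when called higher in NEPs than in both GNPs and NSCs, and NEP-depleted when called lower in both.

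The gene lists numbered 18: SHH pathway and targets, granule neuron progenitor, differentiating neuron, neural stem cell and radial glia, Bergmann glia and astrocyte, oligodendrocyte lineage, GABAergic and Purkinje lineage, microglia and macrophage, endothelial, pericyte with fibroblast and meningeal, erythroid, and ependymal and choroid plexus markers, the Notch pathway, cell cycle, CDK inhibitors and pocket proteins, DNA repair, immediate early and dissociation stress genes, and sex-linked genes. List members outside the genes tested are not analysed here. Lists were tested with limma's camera at a correlation of 0.01, with camera at an estimated correlation and with fry, which asks whether a list's genes move on balance one way, each adjusted over the lists of a comparison. The estimated correlation of a list comes from the fit of all groups, also in comparisons without NEP arrays. The themes cell cycle, DNA repair and quiescence are known from reports on this study, so those lists are not independent evidence of their direction.

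Named genes were, in the NEP with GNP, NEP with NSC, tumor and interaction comparisons, the 5 called genes with the largest rise and the 5 with the largest fall whose groups of arrays did not overlap (for the interaction, without that condition), and up to 2 called members of each list. In the other comparisons they were 3 and 3, and 1 per list. For NEP-enriched and NEP-depleted genes they were the 8 with the largest smaller difference in each direction. Nes, Atoh1, Prom1, Ptch1 and Gli1 were followed everywhere, and genes known only by an identifier were skipped among the largest changes. Other list members named beside a count of 5 or fewer were chosen after their values were seen. The groups, comparisons, tests, lists, rule for named genes and first set of alternative settings were fixed before the data were examined.

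The alternative settings were the mean of all probe sets of a gene, probe sets without the _x_at and _s_at types, no filter on dim probe sets, a filter at the 75 percentile, a second quantile normalization, centring on the array median, a variance trend, robust variance, array weights, only the groups compared, a replicate block, a 2-fold minimum and each array left out in turn. The estimation of the array weights did not converge, so a call gained or lost with array weights alone is no support for a result. After the data were seen, the NEP comparisons were also run with NEP arrays 3 and 4 only and with NEP arrays 1 and 2 only, and the tumor comparison without X and Y genes. The method was tested on simulated data with 200 genes of 12148 changed. Values were independent normal draws, with the same residual SD of a gene in every group. The rates below therefore do not cover correlated genes, groups of unequal spread or unlike arrays within a group. Nor do they cover the larger share of genes called in the data. At a true log2 size of 0.5, 49.3% were called in the right direction in NEP against GNP, 50.7% in NEP against NSC and 61.2% in the tumors. At a true log2 size of 1 the shares were 89.6%, 88.1% and 92.5%, at a size of 2 they were 95.5%, 97.0% and 97.0%, and false calls made up 6.02%, 3.09% and 1.76% of the calls. Every column of values was used.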

Results

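The 19 arrays describe cells of the mouse cerebellum that differ in the marker used to collect them, and tumors that arise when Ptch1, the receptor that holds the Hedgehog pathway in check, is targeted in cells with either marker. The genes behind the labels followed them in part. Nes, which encodes Nestin, had a log2 signal of 5.87 ± 0.19 in NEPs (SD, n = 4), 3.49 ± 0.35 in GNPs (n = 4) and 4.47 ± 0.12 in NSCs (n = 3). Atoh1, the mouse name of Math1 and the transcription factor that specifies granule neuron progenitors, stood at 8.85 ± 0.086 in GNPs and 8.93 ± 0.012 in NSCs, and at 3.95 ± 1.59 in NEPs. Prom1, which encodes CD133, was highest in NEPs at 8.61 ± 0.31, with 8.08 ± 0.11 in NSCs and 7.24 ± 0.17 in GNPs. In NEP tumors and GNP tumors, Atoh1 stood at 10.47 ± 0.15 and 9.43 ± 0.034, and Gli1, a transcriptional target of the Hedgehog pathway, at 8.80 ± 0.21 and 8.47 ± 0.18.

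**Figure D1:**
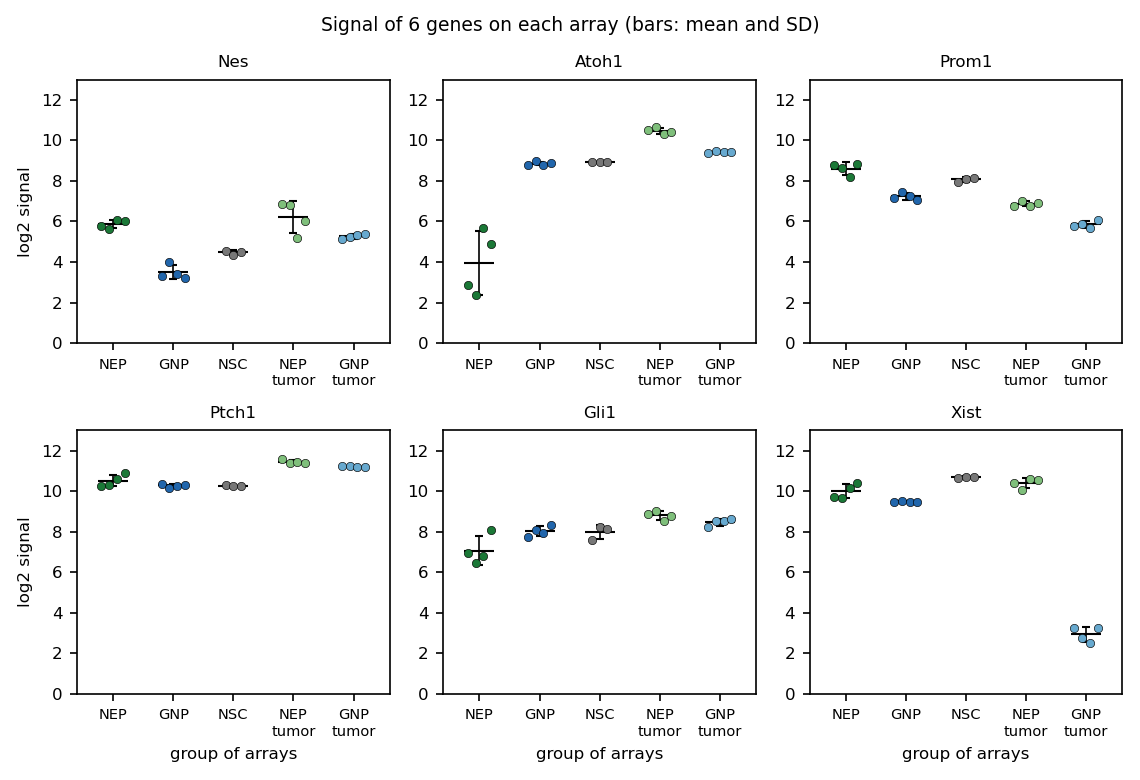
Log2 signal of Nes, Atoh1, Prom1, Ptch1, Gli1 and Xist on each of the 19 arrays, by group, with bars for the mean and SD of a group. Atoh1 is low on the NEP arrays (mean 3.95) and high in the other groups, and Xist is low on the GNP tumor arrays alone (mean 2.94).

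Arrays of a group differed most among NEPs, by the spread of single genes. The median SD of a gene within a group was 0.209 in NEPs, 0.150 in NEP tumors, 0.145 in GNPs, 0.101 in GNP tumors and 0.097 in NSCs. Across genes, which are not independent replicates, NEP arrays 1 and 2 correlated at r = 0.995 and NEP arrays 3 and 4 at 0.988, against 0.940 to 0.943 across these pairs. Microglia and macrophage markers had array medians of 9.15 and 9.23 on NEP arrays 1 and 2, and of 4.23 and 2.33 on NEP arrays 3 and 4, against 1.98 ± 0.11 in GNPs. Pericyte, fibroblast and meningeal markers had array medians of 9.20, 9.30, 5.63 and 5.06 on NEP arrays 1 to 4, against 2.62 ± 0.35 in GNPs and 7.49 ± 0.069 in NSCs. Differentiating neuron markers stood at 4.39, 4.52, 7.58 and 6.57 on NEP arrays 1 to 4, and at 8.72 ± 0.078 in GNPs. NEP tumor arrays 1 and 2 also stood apart from 3 and 4, with Bergmann glia and astrocyte medians of 6.16 and 6.21 against 7.73 and 7.50, and GABAergic and Purkinje lineage medians of 3.11 and 2.95 against 4.13 and 4.24. Xist, expressed from the inactive X chromosome of females, and the Y-linked gene Eif2s3y were both high in NEPs (10.00 and 6.46) and in GNPs (9.49 and 6.90). The 3' minus 5' signal of the actin probe sets was 0.52 in GNPs, 0.55 in NEPs, 0.65 in NSCs, 0.48 in NEP tumors and 0.84 in GNP tumors. It is often read as RNA integrity, a reading that was not checked for the WT kit named by the labels. Among called genes with several probe sets, another probe set was called in the opposite direction for 1.97% of the called genes in NEP against GNP and for up to 5.65% (GNP against NSC).

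The first comparison asked what sets NEPs apart from GNPs. NEPs carried the genes of neural stem cells and radial glia, and GNPs those of the granule lineage, whose list did not pass camera with an estimated correlation (adjusted p = 0.352). Tnc, an extracellular matrix protein of radial glia, had a log2 signal of 10.53 ± 0.30 in NEPs (n = 4) and a dim 2.01 ± 0.43 in GNPs (n = 4), a difference of 8.52, SE 0.24, adjusted p = 6.83e-15. Atoh1 differed by -4.90, SE 0.48, adjusted p = 1.29e-07, and Barhl1, a homeobox gene of the granule lineage, by -5.12, SE 0.48, adjusted p = 6.89e-08. Genes of the cell cycle and of DNA repair were lower in NEPs, by a median of -0.81 and -0.58, with an adjusted p = 0.352 for either list at an estimated correlation, and markers of microglia and mesenchymal cells were higher on the same arrays. Of 12148 genes tested, 8447 were called, 3596 higher and 4851 lower in NEPs. By at least 2-fold, 1909 were higher and 954 lower. The median difference of all genes was -0.11.

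All 17 tested neural stem cell and radial glia markers rose in NEPs, and all 17 did so adjusted over the list alone, with a median of 4.56 (camera adjusted p = 1.48e-11, adjusted p = 0.0133 with an estimated correlation). Besides Tnc they included Ednrb, an endothelin receptor, at 8.18, and Nes at 2.38, SE 0.27, adjusted p = 8.57e-07. Prom1 differed by 1.37, SE 0.13, adjusted p = 1.11e-07. All 17 Bergmann glia and astrocyte markers rose (17 adjusted over the list alone), with a median of 4.63 (camera adjusted p = 4.02e-12, adjusted p = 0.0133 with an estimated correlation). Among them were the water channel Aqp4 at 8.56 and Gdf10, a growth factor of Bergmann glia, at 7.71. In the Notch pathway, 14 of 18 members rose and Hey1, Rbpj and Mfng fell, with the same counts adjusted over the list alone and a median of 1.68 (camera adjusted p = 3.85e-05, adjusted p = 0.0133 with an estimated correlation). The receptor Notch3 rose by 5.85, and Mfng, a glycosyltransferase that modifies Notch receptors, fell by 2.09 on the log2 scale. Pla2g7, a phospholipase, was also among the largest rises, at 8.25, and like Notch3 was dim in GNPs.

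Of 12 granule neuron progenitor markers, 11 fell in NEPs and Zic1 was not called (11 adjusted over the list alone), with a median of -1.96 (camera adjusted p = 0.000539). The adjusted p = 0.352 with an estimated correlation did not pass. Differentiating neuron markers fell in 15 of 18 cases, among them Cbln1, a synaptic organizer, at -5.24, while the adhesion gene Cntn1 rose by 1.04 (15 down and 1 up adjusted over the list alone). Their median was -2.49 (camera adjusted p = 7e-04, adjusted p = 0.418 with an estimated correlation), and the fall was larger on NEP arrays 1 and 2 (array medians 4.39 and 4.52) than on 3 and 4 (7.58 and 6.57). Cadps2, a regulator of vesicle release, the homeobox gene Uncx and the membrane protein Islr2 were among the largest falls, at -5.52, -5.41 and -5.37. GABAergic and Purkinje lineage markers rose in 9 of 12 cases and Lhx1 fell (9 and 1 adjusted over the list alone), with a median of 1.87 (camera adjusted p = 0.000765, adjusted p = 0.352 with an estimated correlation). Ptf1a, the transcription factor that specifies GABAergic neurons of the cerebellum, stood at 10.15 ± 0.26 in NEPs and at a dim 2.07 ± 0.051 in GNPs.

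All 36 tested cell cycle genes fell in NEPs (36 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 1.35e-08). The adjusted p = 0.352 with an estimated correlation did not pass, and the list's theme is known from reports on this study, so its direction is not independent evidence. E2f1 and E2f2, transcription factors that drive entry into S phase, differed by -1.94 and -2.07. The list's array medians were 8.57 ± 0.21 in NEPs and 9.37 ± 0.14 in GNPs. Of 54 DNA repair genes, 43 fell and Xrcc4 rose (43 and 1 adjusted over the list alone), with a median of -0.58 (camera adjusted p = 6.6e-06, adjusted p = 0.352 with an estimated correlation), and this list is not independent evidence either. Rad54l, a helicase of homologous recombination, fell by 1.57 on the log2 scale. Xrcc4, a partner of DNA ligase in end joining, differed by 0.44 and was not called without GNP replicate 2 (0.27), NEP replicate 2 (0.38) or NEP replicate 4 (0.34). Among CDK inhibitors and pocket proteins, Cdkn1c and Rbl2 rose and Cdkn1a, Cdkn1b, Cdkn2c, Cdkn2d and Rb1 fell, of 10 (2 and 5 adjusted over the list alone). The list's median was -0.26. Camera did not pass (adjusted p = 0.588) and fry did, downward (adjusted p = 0.000454). Cdkn1c, which encodes the inhibitor p57, rose by 1.81, and Cdkn1a, which encodes p21, fell by 1.01 on the log2 scale.

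Of 15 SHH pathway genes, Gli3, Sufu, Hhip, Cdon and Igf2 rose and 6 fell (6 and 6 adjusted over the list alone). The list's median of -0.020 and fry pointed down, its mean of 0.249 and camera up, and neither test passed (camera adjusted p = 0.907, fry adjusted p = 0.307). Hhip, a Hedgehog-binding inhibitor of the pathway, rose by 5.85, SE 0.19, adjusted p = 4.09e-14, from a dim signal in GNPs, and Sfrp1, a secreted modulator of Wnt signalling, fell by 4.42 on the log2 scale. Ptch1 differed by 0.24, SE 0.11, adjusted p = 0.054, and was called without NEP replicate 1 (0.32) or NEP replicate 2 (0.30). It was also called with NEP arrays 3 and 4 only (0.46, adjusted p = 0.000446), after a second quantile normalization (0.32, adjusted p = 0.0112), with a filter at the 75 percentile (adjusted p = 0.0488) and with a variance trend (adjusted p = 0.0378). Gli1 differed by -0.97, SE 0.26, adjusted p = 0.00333, and by -0.60 with NEP arrays 3 and 4 only, which ended the call.

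Markers of other cell types rose beside these groups. All 16 microglia and macrophage markers rose (16 adjusted over the list alone), with a median of 4.07 (camera adjusted p = 0.000765, adjusted p = 0.495 with an estimated correlation). Csf1r, a receptor that microglia need, stood at 8.25 ± 3.66 in NEPs and at a dim 2.30 ± 0.23 in GNPs. All 15 pericyte, fibroblast and meningeal markers rose (15 adjusted over the list alone), with a median of 4.08 (camera adjusted p = 1.33e-05, adjusted p = 0.352 with an estimated correlation), among them the collagen genes Col1a2 at 6.76 and Col3a1 at 6.61. Endothelial markers rose in 13 of 14 cases and Slco1a4 fell (13 and 1 adjusted over the list alone), with a median of 2.18 (camera adjusted p = 0.000539, adjusted p = 0.418 with an estimated correlation). Oligodendrocyte lineage markers rose in 10 of 13 cases (11 adjusted over the list alone), with a median of 2.70 (camera adjusted p = 7.2e-05, adjusted p = 0.352 with an estimated correlation), led by the transcription factors Olig1 at 7.39 and Nkx2-2 at 7.01 (dim in GNPs). Ependymal and choroid plexus markers rose in 10 of 11 cases and Otx2 fell (10 and 1 adjusted over the list alone), with a median of 1.43 (camera adjusted p = 0.00336, adjusted p = 0.352 with an estimated correlation). Of 3 erythroid markers, Hbb-b2 and Car2 rose and Hba-a2 fell (camera adjusted p = 0.454, fry adjusted p = 0.000362, upward). Immediate early and dissociation stress genes gave 11 up and 6 down of 20 (camera adjusted p = 0.268, fry adjusted p = 0.0398, upward). Both lists gave the same counts adjusted over the list alone. Of 4 sex-linked genes, Xist and Uty rose and Eif2s3y fell, with the same counts adjusted over the list alone (camera adjusted p = 0.588). Xist was not called without NEP replicate 4 (0.37), nor Eif2s3y without GNP replicate 1 (-0.36) or 3 (-0.41) or NEP replicate 3 (-0.26) or 4 (-0.42). With only the NEP and GNP arrays fitted, neither Eif2s3y nor Xrcc4 was called. With NEP arrays 3 and 4 only, chosen after the data were seen, 7329 genes were called, 6848 of them shared with the full comparison in the same direction.

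**Figure D2:**
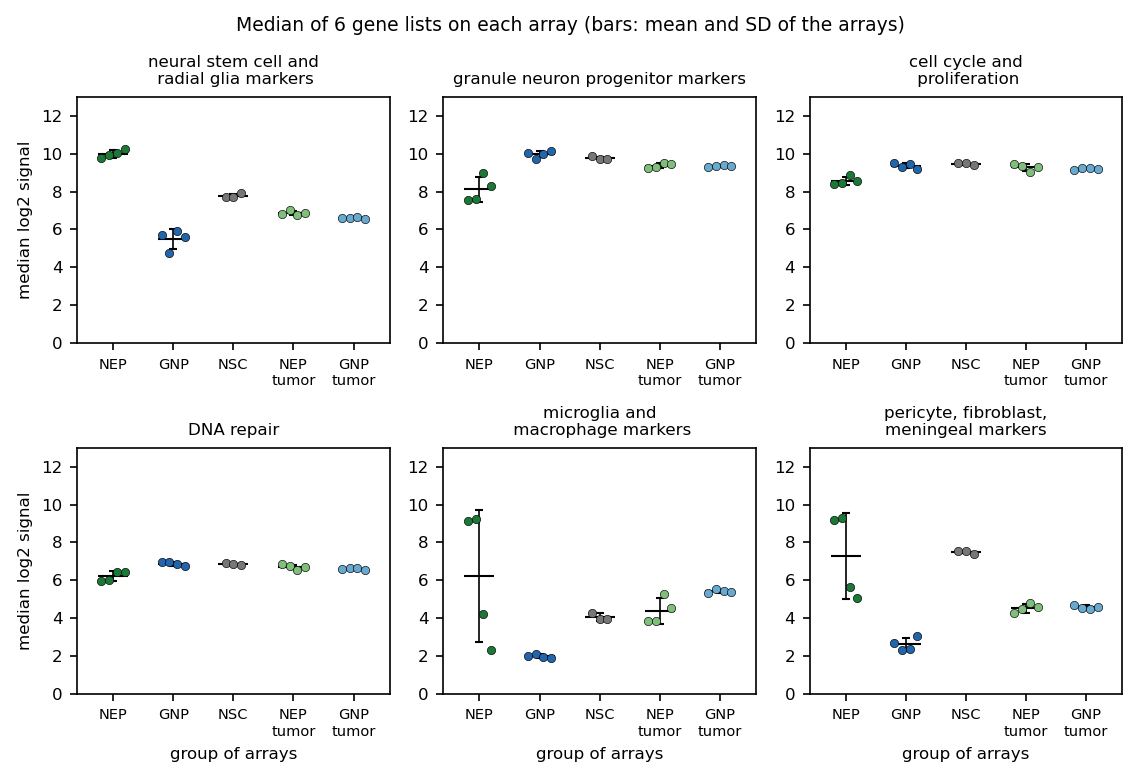
Median log2 signal of the members of 6 gene lists on each of the 19 arrays, by group, with bars for the mean and SD of a group. Neural stem cell and radial glia markers are highest on the NEP arrays, cell cycle and DNA repair genes are lowest there, and microglia and pericyte markers differ between the NEP arrays themselves.

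The second comparison, NEPs against the CD133-positive NSCs, lies across the runs, so group and run cannot be told apart in it. NEPs again had higher glial and stem cell genes and lower granule lineage and cell cycle genes, in lists that passed camera at a correlation of 0.01 and not with an estimated correlation. Gria1, a glutamate receptor subunit, stood at 9.03 ± 0.42 in NEPs (n = 4) and 2.87 ± 0.18 in NSCs (n = 3), a difference of 6.16, SE 0.23, adjusted p = 1.61e-12. Atoh1 was 8.93 ± 0.012 in NSCs, close to its level in GNPs, and differed from NEPs by -4.98, SE 0.52, adjusted p = 4.49e-07. Of 7095 genes called, 3748 were higher and 3347 lower in NEPs. The share called higher was 52.8%, but 47.2% with the mean of all probe sets and 45.2% with a filter at the 75 percentile. By at least 2-fold, 1465 were higher and 663 lower, and the median difference of all genes was 0.017.

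Neural stem cell and radial glia markers rose in 15 of 17 cases (15 adjusted over the list alone), with a median of 1.98 (camera adjusted p = 2.77e-07), among them Tnc at 4.72 and Hopx, a homeodomain protein of radial glia, at 3.92. Bergmann glia and astrocyte markers also rose in 15 of 17 cases (15 adjusted over the list alone), with a median of 1.94 (camera adjusted p = 2.08e-07), led by Gdf10 at 4.67 and the folate enzyme Aldh1l1 at 4.56. In the Notch pathway 12 of 18 members rose, while Hey1 and Mfng fell (13 and 3 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 0.0021). The ligand Dll1 rose by 3.89. All 3 lists had an adjusted p = 0.0697 with an estimated correlation. Nes differed by 1.40, SE 0.29, adjusted p = 0.000638 and Prom1 by 0.53, SE 0.14, adjusted p = 0.00432.

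Granule neuron progenitor markers fell in 11 of 12 cases (11 adjusted over the list alone), with a median of -1.40 (camera adjusted p = 0.000176, adjusted p = 0.355 with an estimated correlation), and Barhl1 differed by -5.29. Cell cycle genes fell in 35 of 36 cases (36 adjusted over the list alone), with a median of -0.77 (camera adjusted p = 2.65e-11, adjusted p = 0.355 with an estimated correlation). DNA repair genes fell in 31 of 54 cases, and Parp1 and Xpc rose (32 down and 2 up adjusted over the list alone), with a median of -0.47 (camera adjusted p = 1.04e-05, adjusted p = 0.524 with an estimated correlation). As above, neither list is independent evidence of its direction. E2f2 differed by -2.08 and Rad54l by -1.64. Xpc was not called without NEP replicate 1 (0.24), 2 (0.24) or 3 (0.26), or NSC replicate 1 (0.28) or 6 (0.18). Differentiating neuron markers fell in 10 of 18 cases, and Cntn1, Map2 and Syt1 rose (10 and 3 adjusted over the list alone), with a median of -1.66 (camera adjusted p = 0.0466, adjusted p = 0.613 with an estimated correlation). That list call was lost without NEP replicate 1 (median -1.38), NEP replicate 2 (-1.48) or NSC replicate 1 (-1.61). It was also lost with NEP arrays 3 and 4 only (-0.79, adjusted p = 0.0579), with only the groups compared (-1.66, adjusted p = 0.149) and with a filter at the 75 percentile (-2.05, adjusted p = 0.0891). Stmn2, a microtubule regulator of growing neurons, fell by 4.11 on the log2 scale. Of 15 SHH pathway genes, Gli3, Sufu, Hhip and Cdon rose and 9 fell (5 and 9 adjusted over the list alone), with a median of -0.34. Camera did not pass (adjusted p = 0.138) and fry did, downward (adjusted p = 7.64e-05). Camera called the list with the mean of all probe sets (-0.48, adjusted p = 0.0353). Ptch1 differed by 0.26, SE 0.11, adjusted p = 0.0594 and was called without NEP replicate 1 (0.34) or 2 (0.32). Other settings that called it were NEP arrays 3 and 4 only (0.48, adjusted p = 0.000588), a second quantile normalization (0.34, adjusted p = 0.0142) and a variance trend (adjusted p = 0.042). Gli1 differed by -0.92, SE 0.28, adjusted p = 0.0102, and by -0.55, not called, with NEP arrays 3 and 4 only.

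Oligodendrocyte lineage markers rose in 8 of 13 cases (9 adjusted over the list alone), with a median of 2.19 (camera adjusted p = 0.00837, adjusted p = 0.558 with an estimated correlation). Their median was 0.63 with NEP arrays 3 and 4 only, which ended the list call. GABAergic and Purkinje lineage markers rose in 6 of 12 cases, and Lhx1, Pcp2 and Foxp2 fell (6 and 3 adjusted over the list alone), with a median of 1.29. Camera did not pass (adjusted p = 0.121) and fry did, upward (adjusted p = 1.49e-05). The list was called with NEP arrays 3 and 4 only (2.16, adjusted p = 0.0287) and with the mean of all probe sets (1.70, adjusted p = 0.031). The risers included Tfap2b, a transcription factor of GABAergic progenitors, at 3.00. CDK inhibitors and pocket proteins rose for Cdkn1c and Rbl2 and fell for Cdkn1a, Cdkn1b, Cdkn2c and Cdkn2d, of 10 (2 and 4 adjusted over the list alone). For this list camera did not pass (adjusted p = 0.29) and fry did, downward (adjusted p = 0.002). Microglia and macrophage markers had a median of 2.20, with Aif1, Mrc1 and Cd14 called higher of 16, 0 adjusted over the list alone by limma and 7 at an unadjusted p under 0.05 (camera adjusted p = 0.121). That list was called without NEP replicate 3 (median 2.89) or 4 (3.35), with array weights (4.26) and with NEP arrays 1 and 2 only (4.98). Cd14 was not called without NEP replicate 1 (1.53) or 2 (1.61), or NSC replicate 1 (2.43), 2 (2.48) or 6 (2.38). Pericyte, fibroblast and meningeal markers, of which Acta2 was called higher (1 adjusted over the list alone), had a median of 0.27 (camera adjusted p = 0.882). It was -1.46, called, with NEP arrays 3 and 4 only, 1.69, called, with 1 and 2 only, and 1.23, called, with array weights. Endothelial markers, of which Slco1a4 and Abcb1a were called lower (1 adjusted over the list alone), had a median of -0.48 (camera adjusted p = 0.218), and of -1.36, called, with NEP arrays 3 and 4 only. Abcb1a was not called without NEP replicate 3 (-0.56) or 4 (-0.85), or NSC replicate 2 (-0.79) or 6 (-0.70). Of the sex-linked genes, Uty, Kdm5d and Eif2s3y were higher and Xist lower in NEPs (3 and 1 adjusted over the list alone; camera adjusted p = 0.0466, adjusted p = 0.247 with an estimated correlation), and the list call was lost without NEP replicate 1 (median 1.91) or 4 (1.95). Kdm5d was dim in NSCs, at 2.21 ± 0.28, and Eif2s3y was not, at 4.73 ± 0.17. With only the NEP and NSC arrays fitted, Gli1, Xpc, Mrc1, Cd14, Abcb1a and Acta2 and the sex-linked list were not called.

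Genes that set NEPs apart from both other progenitor groups address the series' question of a distinct NEP profile. Gria1, the Golgi-associated kinase gene Gask1b, Nkx2-2, the AMPA receptor regulator Cacng5, the collagen gene Col2a1, the myelin glycoprotein gene Omg, the adhesion gene Opcml and Tnc were the 8 most enriched. Their smaller difference ran from 4.72 for Tnc to 6.16 for Gria1, whose level was 9.03 ± 0.42 in NEPs, 1.54 ± 0.23 (dim) in GNPs and 2.87 ± 0.18 in NSCs. Gask1b, Nkx2-2, Col2a1 and Tnc were also dim in GNPs, and Gask1b in NSCs. The 8 most depleted were Islr2, Barhl1, the neurite gene Nrn1, Atoh1, Cadps2, Uncx, the steroid-synthesis enzyme Cyp11a1 and Tbata. The SD between NEP arrays of these 8 ran from 0.64 for Cyp11a1 to 2.70 for Uncx, and that of the 8 enriched genes from 0.13 for Omg to 0.42 for Gria1. Cyp11a1, the most even of the depleted genes, stood at 3.57 ± 0.64 in NEPs, 8.32 ± 0.22 in GNPs and 8.68 ± 0.032 in NSCs.

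In all, 2718 genes were NEP-enriched and 2912 NEP-depleted, of which 1256 and 509 differed at least 2-fold from both groups. The NSC part of this criterion lies across the runs. NEP arrays also differ in markers of other cell types, as given above for microglia and pericytes. Oligodendrocyte lineage markers had array medians of 9.75 and 9.83 on NEP arrays 1 and 2, and of 7.10 and 6.67 on 3 and 4. Independent calls would give 1109 and 1337, but both comparisons use the NEP arrays and so are not independent. With the NEP arrays split so that each comparison used 2 of them, 2283 to 2626 and 2215 to 2668 genes were found over the 6 splits. Among the 8447 genes called between NEPs and GNPs, the NSC mean lay between the NEP and GNP means for 5445, or 64.5%.

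GNPs against NSCs, the third pair of progenitors, also lies across the runs. The granule lineage genes were near the same level and the mesenchymal and glial genes were lower in GNPs, though the mesenchymal list did not pass camera with an estimated correlation (adjusted p = 0.147). Col3a1, a collagen of fibroblasts, stood at 3.99 ± 0.91 in GNPs (n = 4) and 10.96 ± 0.035 in NSCs (n = 3), a difference of -6.97, SE 0.78, adjusted p = 3.89e-06. The matrix proteoglycan gene Dcn differed by -6.70 (dim in GNPs), and Aqp4 by -6.62. Atoh1 differed by -0.076, SE 0.52, adjusted p = 0.925. Of 4409 genes called, 2823 were higher and 1586 lower in GNPs, and by at least 2-fold 280 were higher and 598 lower. The share called higher was 64%, and 76.4% after centring on the array median, while array weights gave 7495 genes.

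Neural stem cell and radial glia markers fell in GNPs in 13 of 17 cases (16 down and 1 up adjusted over the list alone), with a median of -2.69 (camera adjusted p = 2.43e-15, adjusted p = 0.00486 with an estimated correlation), and Ednrb differed by -5.40. Bergmann glia and astrocyte markers fell in 16 of 17 cases (16 adjusted over the list alone; camera adjusted p = 2.28e-14, adjusted p = 0.00686 with an estimated correlation). The Notch pathway had 11 down and Mfng up of 18 (11 and 2 adjusted over the list alone; camera adjusted p = 7.1e-06, adjusted p = 0.00686 with an estimated correlation), with the ligand Jag1 at -2.49. Pericyte, fibroblast and meningeal markers fell in 14 of 15 cases, with a median of -4.48 (14 adjusted over the list alone; camera adjusted p = 1.95e-10, adjusted p = 0.147 with an estimated correlation). Endothelial markers fell in 13 of 14, with a median of -2.43 (13 adjusted over the list alone; camera adjusted p = 4.49e-10, adjusted p = 0.139 with an estimated correlation), among them the tight junction gene Cldn5 at -4.67. Differentiating neuron markers rose in 11 of 18 cases, with a median of 0.94 (11 adjusted over the list alone; camera adjusted p = 0.000568, adjusted p = 0.396 with an estimated correlation), and Syt1, a calcium sensor of vesicle release, rose by 1.45. Of 12 granule neuron progenitor markers, Pax6, Meis1 and Nhlh1 were called higher, with a median of 0.049 (3 adjusted over the list alone; camera adjusted p = 0.696). Nhlh1 was not called without GNP replicate 4 (0.97) or any one NSC array (1.08 to 1.14). Of 36 cell cycle genes, Cdc45 and Bub1b were called higher and Mcm3 lower (2 and 0 adjusted over the list alone). The list's median of -0.021 and camera pointed down, its mean of 0.075 and fry up, and neither passed (camera adjusted p = 0.896, fry adjusted p = 0.714). Nes differed by -0.98, SE 0.29, adjusted p = 0.0157, and was not called without NSC replicate 1 (-0.93) or with the mean of all probe sets (-0.54). Prom1 differed by -0.84, SE 0.14, adjusted p = 0.00026. Of 15 SHH pathway genes, 6 were lower in GNPs and 0 higher (6 and 0 adjusted over the list alone), with a median of -0.13 (camera adjusted p = 0.00629, adjusted p = 0.226 with an estimated correlation, fry adjusted p = 0.00409). Gli1 differed by 0.053, SE 0.28, adjusted p = 0.903 and Ptch1 by 0.022, SE 0.11, adjusted p = 0.898, the last turning to -0.27 with the mean of all its probe sets.

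The comparison of the tumors addressed how alike NEP tumors and GNP tumors are. Ptch1, the gene targeted in both, had a log2 signal of 11.46 ± 0.090 in NEP tumors (n = 4) and 11.21 ± 0.036 in GNP tumors (n = 4), a difference of 0.25, SE 0.11, adjusted p = 0.0983, called with only the tumor groups fitted (adjusted p = 0.0222) or with array weights (adjusted p = 0.00136). The arrays' probe sets lie near the 3' end of transcripts, and one outside the deleted part checks nothing about the deletion. The other probe sets of Ptch1 read 4.32 ± 0.17 and 2.77 ± 0.14 in NEP tumors and 5.36 ± 0.14 and 2.97 ± 0.21 in GNP tumors, so the mean of all its probe sets differed by -0.33, called in the opposite direction (adjusted p = 0.0198). Xist was the largest rise, 10.39 ± 0.25 in NEP tumors and 2.94 ± 0.36 in GNP tumors, and the Y-linked gene Eif2s3y the largest fall, 1.46 ± 0.19 (dim) and 7.57 ± 0.074. Of the 12148 genes, 2861 were called, 1877 higher and 984 lower in NEP tumors, and 190 were higher and 117 lower by at least 2-fold.

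Beside Xist, the largest rises in NEP tumors were Tecta, a matrix protein of the inner ear, at 4.62, the activity-regulated transcription factor Egr3 at 3.85, Cldn34c1, a member of the claudin family, at 3.50, and Nptx1, a secreted neuronal pentraxin, at 3.30 (dim in GNP tumors). The largest falls were Chil3, a chitinase-like protein of macrophages, from 7.24 ± 0.22 in GNP tumors to a dim 2.28 ± 0.11, Mroh2a at -4.28, Arg1, the arginase of alternatively activated macrophages, at -4.20, and Y-linked Kdm5d at -4.12. Arg1 and Kdm5d were dim in NEP tumors. Of 15 SHH pathway genes, 8 were higher in NEP tumors and 0 lower (11 and 0 adjusted over the list alone), with a median of 0.33 (camera adjusted p = 0.0308, adjusted p = 0.727 with an estimated correlation). Hhip rose by 1.29 and Sufu, an inhibitor of the Gli factors, by 0.60, while Gli1 differed by 0.33, SE 0.26, adjusted p = 0.406. Neural stem cell and radial glia markers rose for Nes, Sox9, Prom1, Id1 and Pax3 and fell for Hopx, of 17 (6 and 2 adjusted over the list alone; camera adjusted p = 0.56). Nes differed by 0.95, SE 0.27, adjusted p = 0.0191 and was not called without GNP tumor replicate 1 (0.90) or NEP tumor replicate 1 (0.74) or 2 (0.75), nor with only the tumor groups fitted, and Prom1 differed by 1.02, SE 0.13, adjusted p = 5.56e-05. Atoh1 differed by 1.05, SE 0.48, adjusted p = 0.13, in a fit that shares its variance with the NEP arrays (SD 1.59). It was called with only the tumor groups fitted (1.05, adjusted p = 5.8e-05) and with array weights (0.99, adjusted p = 7.3e-05). In the fit of all groups, Pax6 was the only one of 12 granule neuron progenitor markers called, at 0.92 (1 adjusted over the list alone; camera adjusted p = 0.498). DNA repair genes rose in 7 of 54 cases (6 adjusted over the list alone; camera adjusted p = 0.374), with Nbn, a sensor of DNA breaks, at 0.70. Of 36 cell cycle genes, Ccnb2 and Mcm6 were called higher and Ccna2 and Ccne1 lower (0 adjusted over the list alone by limma and 12 at an unadjusted p under 0.05; camera adjusted p = 0.276). Leaving out any 1 array but NEP tumor replicate 3 ended the call of Ccnb2 (0.23 to 0.27), and any 1 but NEP tumor replicate 2 that of Ccna2 (-0.38 to -0.32). As above, the themes of the DNA repair and cell cycle lists are known, so they are not independent evidence.

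Glial and other markers were also compared between the tumors. Of 17 Bergmann glia and astrocyte markers, S100b rose and Gfap, Gja1, Aldoc and Cst3 fell (2 and 4 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.082, adjusted p = 0.727 with an estimated correlation). At a correlation of 0.01, camera called the list with only the tumor groups fitted (adjusted p = 0.0409), after centring (adjusted p = 0.0375) or without NEP tumor replicate 3 (median -0.41). The array medians were 6.16 and 6.21 on NEP tumor arrays 1 and 2 and 7.73 and 7.50 on 3 and 4, against 7.20 to 7.57 in GNP tumors, so only arrays 1 and 2 lay below every GNP tumor array. Gja1 was not called with the mean of all probe sets (-0.56) or without _x_at and _s_at probe sets (-0.64). In the Notch pathway Dll3 and Hes1 rose and Dll1 fell (2 and 1 adjusted over the list alone). The Notch list's median of 0.013, its mean and fry pointed up and camera down (camera adjusted p = 0.703, fry adjusted p = 0.512), and Hes1, a repressor that Notch activates, rose by 1.38. Of 16 microglia and macrophage markers, 0 were called by limma over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, in a fit whose shared variance includes the unlike NEP arrays. The list's median was -1.04 (camera adjusted p = 0.082, adjusted p = 0.806 with an estimated correlation), and its array medians ran from 3.84 to 5.30 in NEP tumors and from 5.33 to 5.53 in GNP tumors. The list was called by camera with only the tumor groups fitted (median -1.04, adjusted p = 1.35e-07), with array weights (-0.84, adjusted p = 0.00974), after centring (adjusted p = 0.0345), without _x_at and _s_at probe sets (-1.07, adjusted p = 0.0468) or without NEP tumor replicate 3 (-1.21). The pericyte genes Kcnj8 and Abcc9 rose, at 2.20 and 1.48, of 15 on their list (2 adjusted over the list alone). That list's median of -0.20, its mean and camera pointed down and fry up (camera adjusted p = 0.56, fry adjusted p = 0.983). The 4 sex-linked genes tested were all called, Xist up and Uty, Kdm5d and Eif2s3y down (1 and 3 adjusted over the list alone; camera adjusted p = 0.000754, adjusted p = 0.0363 with an estimated correlation). The actin 3' minus 5' signal was 0.84 ± 0.022 in GNP tumors and 0.48 ± 0.058 in NEP tumors. The share of called genes that were higher in NEP tumors was 65.6%, against 55.5% after a second quantile normalization and 75.3% after centring on the array median, and array weights gave 6295 genes.

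Whether the tumors keep the difference between the progenitors was tested over the genes that separated NEPs from GNPs. No shared direction of the tumor difference was detected. The genes used include markers of other cell types on the NEP arrays, with all 16 microglia and all 15 pericyte, fibroblast and meningeal markers higher. The tumor groups also differ in sex-linked genes and in 3' minus 5' signal. The test cannot separate these from a difference kept from the progenitors. Cadps2, at -5.52 between NEPs and GNPs, was higher in NEP tumors (8.34 ± 0.35, n = 4) than in GNP tumors (5.74 ± 0.16, n = 4), an interaction of 8.12, SE 0.65, adjusted p = 1.84e-08. Aqp4 and Tnc, up by 8.56 and 8.52 in NEPs, differed by -1.08 and 0.22 between the tumors, with interactions of -9.63 and -8.30. S1pr3, a sphingosine phosphate receptor, had the lowest interaction of the named genes at -9.72. Over the 8447 genes called between NEPs and GNPs, the 2 differences correlated across genes at Pearson's r = -0.115 and Spearman's rho = -0.0815, with a slope of -0.0313. Permuting the 8 tumor arrays gave an exact two-sided p = 0.429 over 70 assignments, where the smallest possible is 0.0286. The signs were the same for 46.8% of these genes. Of the genes called in both comparisons, 918 moved the same way and 1081 opposite ways, against 949 and 1041 for independent calls. The median absolute difference of these genes was 0.697 between the progenitors and 0.191 between the tumors.

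**Figure D3:**
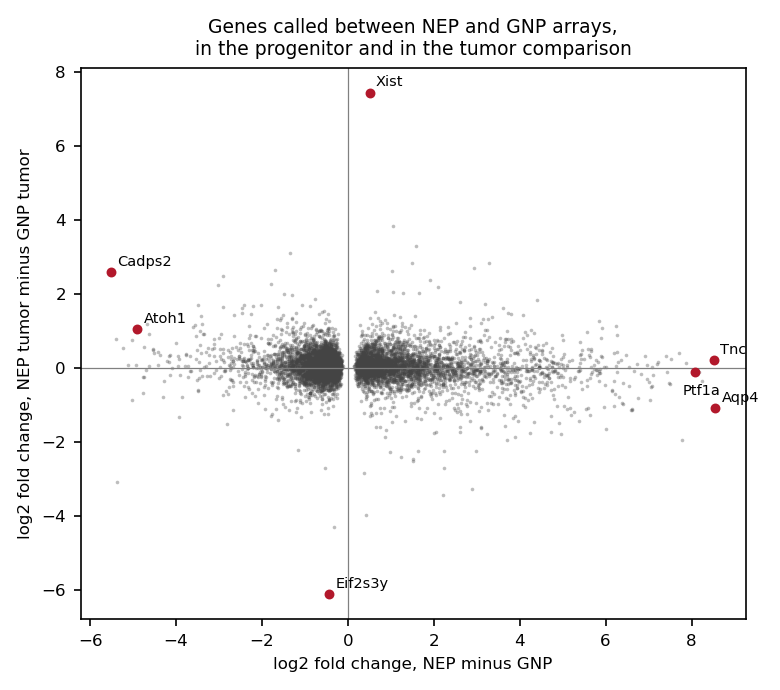
Log2 difference NEP minus GNP (horizontal axis) against NEP tumor minus GNP tumor (vertical axis) for the 8447 genes called between NEPs and GNPs, 1 point per gene, with 7 genes marked in red. Differences between the progenitors reach 8.56 (Aqp4). Those between the tumors are smaller, with a median absolute value of 0.191, and Xist and Eif2s3y stand out. Of these genes, 918 were also called between the tumors in the same direction and 1081 in the opposite one.

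The interaction was called for 7520 genes, 4462 positive and 3058 negative, with a median over all genes of 0.15, and of 0.27 after centring on the array median. All 17 Bergmann glia and astrocyte markers had a negative interaction (17 adjusted over the list alone), with a median of -4.85 (camera adjusted p = 1.39e-13, adjusted p = 0.0121 with an estimated correlation), as had 13 of 17 neural stem cell and radial glia markers (14 adjusted over the list alone; camera adjusted p = 6.98e-11, adjusted p = 0.0121 with an estimated correlation). In the Notch pathway 12 of 18 were negative and Hey1, Rbpj and Mfng positive (12 and 3 adjusted over the list alone; camera adjusted p = 6.43e-05, adjusted p = 0.0163 with an estimated correlation). Granule neuron progenitor markers were positive in 10 of 12 cases (10 adjusted over the list alone; camera adjusted p = 0.000691, adjusted p = 0.349 with an estimated correlation), with Atoh1 at 5.95, SE 0.68, adjusted p = 1.41e-06. Cell cycle genes were positive in 32 of 36 cases (33 adjusted over the list alone; camera adjusted p = 3.76e-06, adjusted p = 0.349 with an estimated correlation) and DNA repair genes in 40 of 54 (40 adjusted over the list alone; camera adjusted p = 6.62e-06, adjusted p = 0.349 with an estimated correlation), and neither list is independent evidence. Exo1, an exonuclease of mismatch repair, had an interaction of 1.94. Microglia and macrophage markers were negative in 14 of 16 cases (16 adjusted over the list alone; camera adjusted p = 0.000383, adjusted p = 0.421 with an estimated correlation) and pericyte, fibroblast and meningeal markers in 14 of 15 (14 adjusted over the list alone; camera adjusted p = 5.87e-05, adjusted p = 0.349 with an estimated correlation). SHH pathway genes gave 8 positive interactions, and negative ones for Gli3, Hhip, Cdon and Igf2 (8 and 4 adjusted over the list alone). Their median of 0.34, camera and fry pointed up and their mean of -0.0080 down. Fry passed and camera did not (fry adjusted p = 0.000946, camera adjusted p = 0.354). Nes had an interaction of -1.43, SE 0.39, adjusted p = 0.00421, Gli1 of 1.30, SE 0.37, adjusted p = 0.00599, Prom1 of -0.36, SE 0.19, adjusted p = 0.11 and Ptch1 of 0.012, SE 0.15, adjusted p = 0.947. Prom1 was called without NEP replicate 3 (-0.50), after a second quantile normalization (-0.54), with array weights (-0.37) and with NEP arrays 1 and 2 only (-0.45). Ptch1 turned to -0.44, called, with the mean of all its probe sets, and was called at 0.23 with NEP arrays 1 and 2 only.

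Correlations between whole arrays measured how alike the groups were. The mean correlation between NEP tumor and GNP tumor arrays was 0.983, against 0.994 within the groups, a gap of 0.0118. Between NEP and GNP arrays it was 0.853, against 0.976 within the groups, a gap of 0.123. An exact one-sided permutation of the arrays gave p = 0.0286 for each gap, the smallest that 8 arrays allow. NEP tumor arrays correlated with GNP arrays at 0.949 and with NEP arrays at 0.865, and GNP tumor arrays with GNP arrays at 0.944 and with NEP arrays at 0.869. NEP and GNP arrays were of one run and tumor arrays of the other. These correlations are across genes, which are not independent replicates.

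NEP tumors against NEPs, a comparison across the runs, showed higher granule lineage genes and lower stem cell and glial genes. These lists passed camera only at a correlation of 0.01, and not with an estimated correlation. Atoh1 rose from 3.95 ± 1.59 in NEPs (n = 4) to 10.47 ± 0.15 in NEP tumors (n = 4), a difference of 6.52, SE 0.48, adjusted p = 3.1e-09. Tbata, also depleted in NEPs, rose by 7.21 and the guidance cue Sema3e by 6.46 (dim in NEPs). Ptf1a differed by -8.26, with a dim signal in the tumors, and Tnc by -7.41. The glutamate receptor gene Grm3 went from 10.06 ± 0.47 in NEPs to a dim 2.46 ± 0.36 in the tumors. In all, 8365 genes were called, 4399 up and 3966 down, and by at least 2-fold 1070 up and 1864 down.

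Granule neuron progenitor markers rose in 8 of 12 cases and Mfap4 fell (8 and 1 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 0.028, adjusted p = 0.527 with an estimated correlation). That list call was lost without NEP tumor replicate 3 (0.75) or with a filter at the 75 percentile (0.77). Neural stem cell and radial glia markers fell in 15 of 17 cases and Sox9 rose (15 and 1 adjusted over the list alone), with a median of -2.66 (camera adjusted p = 1.93e-07, adjusted p = 0.0624 with an estimated correlation). Bergmann glia and astrocyte markers fell in 15 of 17 and S100b rose (16 and 1 adjusted over the list alone; camera adjusted p = 2.38e-06, adjusted p = 0.0703 with an estimated correlation), with Aldh1l1 at -6.93. Cell cycle genes rose in 32 of 36 cases and Ccne1 fell (32 and 1 adjusted over the list alone), with a median of 0.60 (camera adjusted p = 6.61e-06, adjusted p = 0.527 with an estimated correlation), and DNA repair genes rose in 37 of 54 and Lig3 and Prkdc fell (37 and 2 adjusted over the list alone; camera adjusted p = 0.000278, adjusted p = 0.527 with an estimated correlation), lists that are not independent evidence. CDK inhibitors and pocket proteins rose in 8 of 10 cases and Cdkn1c fell (8 and 1 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 0.0104, adjusted p = 0.0624 with an estimated correlation), a list call lost with a filter at the 75 percentile (0.78). Cdkn2a, the locus of the inhibitor p16 and of Arf, rose from a dim 1.79 ± 0.13 to 6.19 ± 0.96. Immediate early and dissociation stress genes rose in 15 of 20 cases and Nr4a1 fell (15 and 2 adjusted over the list alone), with a median of 1.46 (camera adjusted p = 0.00121, adjusted p = 0.246 with an estimated correlation), and Fosb rose by 3.99. Pericyte, fibroblast and meningeal markers fell in 13 of 15 cases and Kcnj8 rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.0104, adjusted p = 0.527 with an estimated correlation). Their median of -2.94 became -0.83 with NEP arrays 3 and 4 only, which ended the list call. Microglia and macrophage markers, of which Cx3cr1, Csf1r and Mrc1 were called lower (1 adjusted over the list alone), had a median of -1.62 (camera adjusted p = 0.167) and of 1.24, called, with NEP arrays 3 and 4 only, and were called without NEP replicate 4 (median -2.86), with array weights (-3.54) and with NEP arrays 1 and 2 only (-4.49). Ptch1 rose by 0.94, SE 0.11, adjusted p = 5.87e-07 and Gli1 by 1.74, SE 0.26, adjusted p = 1.75e-05, and Prom1 fell by 1.75 on the log2 scale. Nes differed by 0.34, SE 0.27, adjusted p = 0.279, and was called without NEP tumor replicate 3 (0.69).

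GNP tumors against GNPs, likewise across the runs, showed macrophage, glial and stress genes higher in the tumors. The macrophage list did not pass camera with an estimated correlation (adjusted p = 0.579). That correlation, 0.97, comes from the fit of all groups, with the unlike NEP arrays in it. The list's array medians were 1.875 to 2.125 in GNPs and 5.33 to 5.53 in GNP tumors. The 3' minus 5' signal rose too, from 0.52 to 0.84 for actin and from 0.0058 to 0.32 for Gapdh. Lyz1, a lysozyme gene, rose from a dim 2.15 ± 0.10 in GNPs (n = 4) to 9.64 ± 0.059 in GNP tumors (n = 4), a difference of 7.49, SE 0.98, adjusted p = 7.93e-06. The microglial protease gene Ctss rose by 7.16 and H2-Aa, an MHC class II gene, by 6.90, both dim in GNPs. Xist differed by -6.55, the netrin receptor gene Unc5c by -6.37 and Mfap4, a gene of the granule progenitor list, by -6.35. In all, 6055 genes were called, 2245 up and 3810 down, and by at least 2-fold 723 up and 744 down.

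Immediate early and dissociation stress genes rose in 17 of 20 cases (17 adjusted over the list alone), with a median of 1.59 (camera adjusted p = 4.45e-11, adjusted p = 0.0227 with an estimated correlation), and Atf3, a stress-induced transcription factor, rose by 5.05. Bergmann glia and astrocyte markers rose in 13 of 17 cases and Gja1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 8.14e-10, adjusted p = 0.0227 with an estimated correlation), with S100b at 5.86 (dim in GNPs). CDK inhibitors and pocket proteins rose in 6 of 10 cases (6 up and 1 down adjusted over the list alone; camera adjusted p = 0.000559, adjusted p = 0.0227 with an estimated correlation), and Cdkn2a rose from a dim 1.85 ± 0.11 to 6.69 ± 0.10. Microglia and macrophage markers rose in 10 of 16 cases (11 adjusted over the list alone), with a median of 3.72 (camera adjusted p = 0.000312, adjusted p = 0.579 with an estimated correlation). Neural stem cell and radial glia markers rose in 11 of 17 cases, and Vim, Prom1, Msi2 and Pax3 fell (12 and 4 adjusted over the list alone; camera adjusted p = 0.000559, adjusted p = 0.201 with an estimated correlation). Cell cycle genes, again not independent evidence, fell in 9 of 36 cases (8 adjusted over the list alone; camera adjusted p = 0.196, and 0.0368 with array weights) and DNA repair genes in 23 of 54, with Xpc called higher (21 and 0 adjusted over the list alone; camera adjusted p = 0.0264, adjusted p = 0.759 with an estimated correlation). The DNA repair call was lost after a second quantile normalization (median -0.22). Ptch1 rose by 0.93, SE 0.11, adjusted p = 1.49e-06 and Nes by 1.77, SE 0.27, adjusted p = 4.29e-05, and Prom1 fell by 1.39 on the log2 scale. Atoh1 differed by 0.57, SE 0.48, adjusted p = 0.344 and Gli1 by 0.44, SE 0.26, adjusted p = 0.182. Both were called with only these groups fitted (0.57, adjusted p = 3.97e-05 and 0.44, adjusted p = 0.0161) and with array weights (0.62, adjusted p = 0.00291 and 0.53, adjusted p = 0.0013). SHH pathway genes rose for Ptch1, Hhip, Ccnd1 and Igf2 and fell for Gli2 and Gli3, of 15 (4 and 2 adjusted over the list alone). Their median of -0.026 pointed down and their mean of 0.189, camera and fry up (camera adjusted p = 0.356).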

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

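The tests of microglia, of other non-cycling cells, of NSC arrays as GNP arrays, of the run and of RNA quality were chosen after the results were seen, and the count of tumor genes without X and Y genes and the settings with 2 NEP arrays only were added after the data were seen.

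Some arrays lay far from the other 3 of their group by the gap test of Dixon, with the range of the others given in parentheses. Among lists and array measures these were the GABAergic and Purkinje lineage markers list at 3.28 on GNP replicate 3 (3.06 to 3.09), the immediate early and dissociation stress genes list at 4.94 on GNP replicate 4 (6.49 to 6.69), the sex-linked genes list at 1.57 on NEP tumor replicate 3 (1.25 to 1.29) and the poly-A spike-in mean at 7.003 on GNP tumor replicate 2 (6.66 to 6.69). Chance alone singles out about 1 group in 20. Of 80 groups of arrays tested for list medians and array measures, 4 held such an array, and of 504 groups tested over 126 named genes, 25 did.

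Among named genes, more of these arrays were GNP replicate 4 than any other. It lay above the other GNP arrays for Aqp4 at 4.67 (2.09 to 2.12), Car2 at 4.99 (3.38 to 3.45), Col3a1 at 5.35 (3.45 to 3.63), Ednrb at 4.17 (2.00 to 2.28), Olig1 at 3.42 (2.43 to 2.60) and Sostdc1 at 3.08 (2.33 to 2.42). It lay below them for Cldn34c1 at 5.92 (6.95 to 7.04), Cyp11a1 at 7.99 (8.38 to 8.46), Fosb at 3.92 (6.80 to 7.07), Hspa1b at 3.71 (6.08 to 6.31) and Sfrp1 at 10.36 (10.75 to 10.81). Values far from those of their group on other arrays were Cdkn2b at 4.71 on NEP tumor replicate 2 (4.38 to 4.41), Cldn5 at 6.19 on GNP tumor replicate 1 (5.70 to 5.73), Ednrb at 10.23 on NEP replicate 1 (11.03 to 11.10), Gja1 at 9.56 on GNP replicate 1 (9.43 to 9.44) and Gpr17 at 2.96 on GNP tumor replicate 4 (3.26 to 3.32). Among them were also H2-Aa at 9.02 on GNP tumor replicate 3 (8.88 to 8.90), Islr2 at 9.99 on GNP replicate 1 (10.18 to 10.21), Pla2g7 at 5.47 on GNP tumor replicate 3 (5.84 to 5.86), Ptf1a at 2.15 on GNP replicate 2 (2.04 to 2.05) and Ramp2 at 6.54 on GNP tumor replicate 4 (6.29 to 6.32). Further cases were Ramp2 at 6.90 on NEP tumor replicate 2 (6.48 to 6.55), Sufu at 9.30 on NEP replicate 3 (8.96 to 9.02), Tbata at 10.13 on NEP tumor replicate 3 (10.33 to 10.36) and Xrcc4 at 4.56 on GNP replicate 2 (5.22 to 5.24).

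The interaction tested whether the tumor difference is unequal to the progenitor difference, and it was called for 7520 genes. The list median of the interaction was 2.44 for granule neuron progenitor markers, 2.41 for differentiating neuron markers, 0.77 for cell cycle and proliferation and 0.71 for DNA repair. It was -4.81 for neural stem cell and radial glia markers, -4.85 for Bergmann glia and astrocyte markers, -1.56 for Notch pathway, -3.24 for oligodendrocyte lineage markers and -1.24 for GABAergic and Purkinje lineage markers. It was also -5.22 for microglia and macrophage markers, -1.70 for endothelial markers, -4.71 for pericyte, fibroblast and meningeal markers, -1.61 for ependymal and choroid plexus markers and -4.24 for sex-linked genes. These 14 lists passed camera at a correlation of 0.01. With an estimated correlation 3 of them passed: the stem cell, Bergmann glia and Notch lists.

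Among named genes, the tumor difference exceeded the progenitor difference for Cadps2 (8.12), Xist (6.95), Uncx (6.21), Atoh1 (5.95), Tbata (5.90), Sfrp1 (4.84), Barhl1 (5.202), Cbln1 (5.78), Hey1 (1.90) and E2f2 (1.91). The same held for Cdc45 (1.85), Cdkn1a (0.86), Exo1 (1.94), Rad54l (1.82), Pdgfra (0.62), Pcp4 (1.85), Slco1a4 (2.31), Hba-a2 (0.54), Otx2 (2.38), Egr2 (1.31) and Gli1 (1.30). It lay below the progenitor difference for S1pr3 (-9.72), Aqp4 (-9.63), Pla2g7 (-8.59), Tnc (-8.30), Ednrb (-8.28), Igf2 (-6.80), Cntn1 (-1.09), Aldoc (-7.88), Dll1 (-6.04), Cdkn1c (-1.62) and Nkx2-2 (-7.39), and for Ptf1a (-8.19), Csf1r (-7.002), Ctss (-6.89), Cldn5 (-3.50), Col3a1 (-7.72), Col1a2 (-7.56), Car2 (-3.57), Sostdc1 (-3.81), Zfp36 (-3.94), Eif2s3y (-5.67) and Nes (-1.43). The call was lost for Otx2 without GNP replicate 1 (2.31), without NEP replicate 1 (1.87), without NEP replicate 2 (1.71), without GNP tumor replicate 4 (2.36), without NEP tumor replicate 1 (2.26) and without NEP tumor replicate 2 (2.29), and with NEP arrays 3 and 4 only (0.60, adjusted p = 0.12). It was lost for Pdgfra without NEP replicate 3 (0.46), without NEP replicate 4 (0.51) and without NEP tumor replicate 3 (0.52), after a second quantile normalization (0.50), and with NEP arrays 1 and 2 only (0.21, adjusted p = 0.184). A difference in sex between donors enters the values of Xist and Eif2s3y.

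Other splits of the same arrays tested whether chance groupings give as many genes. In each comparison 1 split, the real one, gave as many. A random labelling of these arrays is therefore an unlikely source of the counts. Chance differences between animals are not excluded, since nothing states that the arrays of a group come from separate animals. Of 35 splits each, the real and the highest other count were 8447 and 2076 for NEP against GNP, 7095 and 6366 for NEP against NSC, 4409 and 1974 for GNP against NSC, 2861 and 2 for the tumors, 8365 and 2345 for NEP tumor against NEP, and 6055 and 1 for GNP tumor against GNP. Of 100 splits drawn, they were 7520 and 6179 for the interaction, and 2718 and 967 for NEP-enriched genes. The split with 6366 genes put NEP replicate 3 with the NSC arrays, and that with 1974 put GNP replicate 4 with them.

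Cell cycle genes were lower on NEP than on GNP arrays. Against microglia as the whole cause, the list's median was -0.62 with the 2 NEP arrays that carry fewer microglia genes, with an SD of 0.164 over 8 pairs of arrays. Against the scaling, the highest median over 3 scalings was -0.73, and the list lay -0.69, -0.63 and -0.69 from the median of all genes. Non-cycling cells other than microglia stay open, since the lowest mesenchymal marker median among NEP arrays lay 1.99 above the highest GNP array, and no value separates their share from a slower cycle. A slower cycle of the NEPs themselves is a biological explanation that was not tested.

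NSC arrays carried granule lineage genes near the GNP level. They are not GNP arrays under another name, as their mesenchymal markers lay 4.87 above those of GNPs. A mixture of granule lineage RNA and RNA of NEP-like cells may contribute, but is not shown. The median NSC to GNP ratio of 244 genes at least 4-fold lower in NEPs was 0.638. The NSC to NEP ratio of 954 genes at least 4-fold higher was 0.248. They summed to 0.886 (SD 0.0221 over 1000 resamplings of genes, which are not independent). The shares of a mixture of these alone would add up to the whole, and the sum lay below that. Atoh1, at 8.93 in NSCs and 8.85 in GNPs, lies above what a share of 0.638 would give. SHH pathway genes had a higher list median in NSCs (9.62 ± 0.020) than in GNPs (9.14 ± 0.15) and NEPs (8.65 ± 0.23). That median decides nothing, since members of the list differed both ways between NEPs and GNPs (5 up and 6 down). A mixture bounds each gene between its sources, but not the median of such a list. The labels do not list the lineage markers used to remove cells. The run, with poly-A spike-ins 2.19 apart, cannot be told apart from the group, and a CD133-positive population that expresses granule lineage genes stays open, untested.

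Sex-linked genes separated the tumor groups. Of the 2861 genes called, 93 lay on X or Y and 2768 (96.7%) elsewhere. With 407 genes tested on X or Y, leaving them out could not have removed most of the calls, so this count decides nothing about donor sex. Donor sex cannot be told apart from the tumor group, as each group shows the signal of 1 sex. RNA quality cannot be told apart from the group: the actin 3' minus 5' signal differed by -0.36 between the tumors, while across genes, which are not independent replicates, folds correlated with the slope on that signal within NEP tumors at r = -0.059 and within GNP tumors at 0.014. A difference between tumors by cell of origin stays open, untested.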

How the results depend on the processing

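The settings with NEP arrays 3 and 4 only, with NEP arrays 1 and 2 only and without X and Y genes were chosen after the data were seen.

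Over 266 named gene results, 5684 values were computed under alternative settings. Of these, 5533 kept their side of the threshold and, where called, their direction. A value called in neither setting was counted as the same whatever its direction. A further 121 kept the direction and were no longer called, 26 kept it and became called, and 4 reversed. Over 126 list results, 2513 values were computed, of which 2424 were the same by that rule, 46 were no longer called, 41 became called and 2 reversed. Over 13 counts and correlations, 260 of 270 values stayed the same, counts within 1.5 times of the reported one.

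A 2-fold minimum gave 2863 genes for NEP against GNP, 2128 for NEP against NSC, 878 for GNP against NSC, 307 for the tumors, 3251 for the interaction, 2934 for NEP tumor against NEP and 1467 for GNP tumor against GNP. These fall because the setting asks for more. A filter at the 75 percentile left 1651 NEP-enriched genes, with fewer genes tested. Array weights raised GNP against NSC to 7495 genes and the tumors to 6295. Their estimation did not converge, and the cause was not tested.

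The mean of all probe sets reversed Ptch1, to -0.27 in GNP against NSC, -0.33 in the tumors and -0.44 in the interaction, because a dimmer probe set moved the other way. NEP arrays 3 and 4 only reversed the pericyte, fibroblast and meningeal list in NEP against NSC (-1.46), the microglia and macrophage list in NEP tumor against NEP (1.24) and Cd14 in NEP against NSC (-0.13). The setting leaves out the 2 NEP arrays with the highest signal of those lists and of Cd14.

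With each array left out in turn, NEP against GNP gave 7924 to 8564 genes, NEP against NSC 6243 to 7482, GNP against NSC 3410 to 4140, the tumors 2120 to 2822, the interaction 7086 to 7867, NEP tumor against NEP 7862 to 8547 and GNP tumor against GNP 5402 to 5696. NEP-enriched genes numbered 2477 to 3001 and NEP-depleted genes 2572 to 3113. The origin signature in tumors, the correlation between the progenitor and tumor differences, ran from -0.145 to -0.0903, and the gap in correlation within and between groups from 0.0106 to 0.0130 for tumors and from 0.116 to 0.146 for NEPs and GNPs.

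NEP arrays 3 and 4 only gave 7329 genes against GNP, 6411 against NSC, 6904 for the interaction and 7483 for NEP tumor against NEP. NEP arrays 1 and 2 only gave 8740, 7928, 8280 and 8755. Arrays of the same number in NEPs and GNPs, and in the 2 tumor groups, deviated from their group means with correlations across genes of -0.158 to 0.071, and so were not taken as pairs. NEP and GNP arrays of the same number have neighbouring numbers in the titles, and array 4 had the highest poly-A spike-ins of both groups (9.13 and 9.07), so a shared step of processing stays possible. Taking the number as a replicate block gave 8402, 7008, 4298, 2695, 7422, 8293 and 5952 genes in the order of the comparisons, 2732 NEP-enriched genes and 2841 NEP-depleted genes. The median of all genes in the interaction was 0.15, and 0.27 after centring on the array median. Signal over background limits the dim genes, whose folds are folds of array signal.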

Other observations

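Cd74 and the MHC class II genes below were chosen after their values were seen, and no explanation was tested.

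Cd74, the invariant chain of MHC class II, which presents antigen on myeloid cells, was lower in NEP tumors (n = 4) than in GNP tumors (n = 4). It had a log2 signal of 5.64 ± 0.20 and 8.04 ± 0.14, a difference of -2.41, SE 0.51, adjusted p = 0.00273 by limma. H2-Aa differed by -2.25 (adjusted p = 0.0095), H2-Ab1 by -2.26 (5.68e-05), H2-Eb1 by -2.38 (3.75e-05), H2-DMa by -0.62 (0.00604) and H2-Ea, not called, by -0.35 (0.103). No list of class II genes was tested. Of the 16 microglia and macrophage markers, 0 were called by limma in the fit of all groups, and 0 had an unadjusted p under 0.05. Their list was lower too, with a median of -1.04 and array medians of 3.84 to 5.30 in NEP tumors and 5.33 to 5.53 in GNP tumors. Camera called that list with only the tumor groups fitted (adjusted p = 1.35e-07), and not with all groups fitted (adjusted p = 0.082, and 0.806 with an estimated correlation of 0.97).

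Cdkn2a was near background on progenitor arrays, at 1.79 in NEPs, 1.85 in GNPs and 1.91 in NSCs, and stood at 6.19 ± 0.96 in NEP tumors and 6.69 ± 0.10 in GNP tumors. Tumor and NSC arrays are of the same run.

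Xist and Y-linked Eif2s3y were both above the array median in NEPs, GNPs and NSCs. NSC arrays had Xist at 10.69, Eif2s3y at 4.73 and a dim Kdm5d at 2.21, NEP tumors Xist at 10.39 and a dim Eif2s3y at 1.46, and GNP tumors Xist at 2.94 and Eif2s3y at 7.57.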
